A study of Drosophila melanogaster with 3 samples.

How the data were processed

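Chromatin bound by GFP-tagged CG14710 was immunoprecipitated with an antibody against GFP from whole Drosophila melanogaster embryos of mixed sex, 0 to 14 hours old, in 3 biological replicates of 1 group. Per the labels, the chromatin was in fragments of 200 to 800 bp. The 5 peak lists used were in narrowPeak format: 1 per replicate, the authors' pooled list and the authors' list thresholded on the irreproducible discovery rate (IDR). According to the text files that came with them, each replicate list was made by the authors from that replicate's alignments to the dm6 assembly and 1 control file used for all replicates, and the IDR list was derived from the 3 replicate lists and the pooled list. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. Alignments, coverage tracks and reads were not analysed here, so read depth per sample is unknown.

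The signal value of each peak was computed by the authors' peak caller before the lists were deposited. Its scale is not stated, so signal was used only to rank, describe or filter peaks within a list, and lists were compared by rank or percentile. The q value of each peak was deposited by the authors as -log10 and was capped at a shared highest value per list, between 3.94 and 4.4, which 29.8% to 43.3% of the peaks of a replicate list and all IDR peaks held. It was not used in any comparison. The summit position was deposited by the authors as an offset from the interval's start, and in 2 to 17 lines per list this offset lay at or past the interval's end. Because each replicate list held exactly 30000 peaks, a site missing from a list was read as not among its 30000, not as unbound.

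Summits on the arms 2L, 2R, 3L, 3R, 4, X and Y were set against the RefSeq annotation of the same assembly, with 17833 genes and 23660 transcription start sites (TSS). A promoter was the window of 500 bp on each side of a TSS of any gene for the region classes, and of a protein-coding gene for the gene lists. For each pair of replicates, the 9194 peaks with the highest signal, as many as the IDR list holds, were compared in both directions. Region shares were tested against shares of bases weighted by the peaks per chromosome, and arms against their length, by two-sided exact binomial tests. The 19 gene lists and 22 motif sequences were fixed before the data were examined. Gene lists were tested against all other protein-coding genes by two-sided Fisher's exact tests, with 0.5 added to each cell for the odds ratio. Motifs within 50 bp of a summit, on either strand, were compared with a window centred 500 bp to the left or right of the same summit, the side drawn with a fixed seed, by two-sided exact McNemar tests, with 0.5 added to each discordant count for the odds ratio. The open search ranked all 8-mers on 2L, 2R and 4 and tested the first 20 again on 3L, 3R, X and Y. Each family of tests was adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Permutation tests of a trend over bins drew 100000 two-sided permutations. Intervals are 95% Wilson intervals and, like the tests on peaks and genes, cover counting error only, since neighbouring peaks and genes are not independent.

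Named sites were chosen by a rule fixed before the data were examined: the gene with the nearest TSS at each of the 25 IDR peaks with the highest mean percentile over the replicates, CG14710, the 4 bound members with the highest signal of each list that passed and 2 of each other list, and the 5 motifs and 5 8-mers with the largest odds ratios. A gene that this rule also took is not reported here. A peak took a replicate's value from the highest peak of that replicate over its summit, so summits within 1 broad interval share a value.

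Alternatives were other list sizes and overlap rules, TSS windows of 250 and 1000 bp, the 50% of peaks with the higher signal, each replicate left out in turn, other backgrounds, dinucleotide-shuffled windows, windows of 100 bp on each side, peaks away from promoters and summits outside soft-masked repeats. Each window was paired with a shuffled copy for motifs and 8-mers, and 10 copies of each were made for the sequence found at the 100 strongest peaks. Alternatives added after seeing the data were the lists and motifs without the 100 strongest peaks, the gene lists without the histone genes, the chorion list without Cp190, the overlap of the 100 strongest peaks, and the gene lists in the 9194 strongest peaks of each replicate alone. For regions, gene lists, motifs and 8-mers, leaving out a replicate meant keeping the IDR peaks among the strongest of the other 2, and the IDR list was made from all 3. The procedures were tested on simulated data: a planted 8-mer, a planted motif and 3 of 3 planted gene lists were recovered, with 0 other motifs or lists passing and 0 8-mers passing when nothing was planted. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.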

Results

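Chromatin immunoprecipitation followed by sequencing (ChIP-seq) measured where the protein of the Drosophila melanogaster gene CG14710 lay along the genome of whole embryos. The embryos were of both sexes, collected 0 to 14 hours after egg laying, from a transgenic line whose CG14710 protein carried green fluorescent protein (GFP) at its C-terminus, and an antibody against GFP pulled down the bound chromatin. The study had 1 group of 3 biological replicates and no second genotype, stage or target, so the comparisons are between replicates, between parts of the genome and between sets of genes. Each replicate list and the authors' pooled list held 30000 peaks, and the list that passed the authors' irreproducible discovery rate (IDR) filter held 9194. Each IDR peak was also a peak of the pooled list, and together they were the 9194 pooled peaks with the highest signal value. Read depth per replicate is not given in the sources used here. Signal values are those of the authors' peak caller and serve below to rank and describe peaks within a list.

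The strongest sites lay at promoters. All 25 sites chosen by their mean rank over the 3 replicates had their summit within 500 bp of the transcription start site (TSS) of a protein-coding gene, from -320 to 25 bp, and 16 of the 25 lay within 100 bp. The first was at CG3764 on 3L, 17011659 to 17013485 (dm6), where the summit lay at -65 bp from the TSS and the pooled signal was 85632. This peak ranked first in every replicate, with signals of 32184, 23698 and 29871. It was followed by the AMPK-related kinase gene Nuak (3R, 10263391 to 10264911; pooled signal 61864), CG1317 (58563), CG15435 (55810), CG7275 (55191) and the ubiquitin ligase subunit gene Roc2 (52684). Other genes of protein turnover among the 25 were Uch, which encodes a ubiquitin hydrolase (50708), the p97 cofactor gene p47 (39720) and the cathepsin gene CtsB (37980). Genes of organelles included Opa1, required for mitochondrial fusion (52425), and the peroxisome import gene Pex19 (41842). Genes of RNA and transcription were the TFIIH subunit gene Ssl1 (40727), the menin gene Mnn1 (38346), the mRNA export gene Rae1 (38163), the translation initiation gene eIF4H1 (36185) and the ribosome biogenesis gene Surf6 (44397). The caspase inhibitor gene Diap1 had a signal of 43719, the phosphatase gene PpV 42917 and the receptor gene mthl1 41897. The remaining named sites were CG13339 (48246), CG3038 (43441), CG11089 (40339), m-cup (38808), CG17141 (37199) and RpL27A. The RpL27A site is uncertain, because its summit had a pooled signal of 766 and took its replicate ranks from the interval it shares with CG15435 on 2L, 4458154 to 4460438. Mean percentiles of the 25 sites within the replicate lists were at least 99.9. Each site is named by its nearest TSS only, and a peak can lie at the promoters of several genes. The Ssl1 peak also lay at the promoter of Chro, and the CG15435 peak at that of mRpL27.

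Signal fell steeply over the first 100 ranks. The peak at rank 50 was 3.39 ± 0.194 times as high as the peak at rank 100 (SD, n = 3 replicates) and 11 ± 1.73 times as high as the peak at rank 500. Of the 100 IDR peaks with the highest signal, 98 lay within 500 bp of a TSS (95% Wilson interval 93.0% to 99.4%), against 68.5% (63.8% to 72.9%) of the next 400 peaks and 49.1% (47.6% to 50.6%) of the 4194 peaks with the lowest signal.

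**Figure D1:**
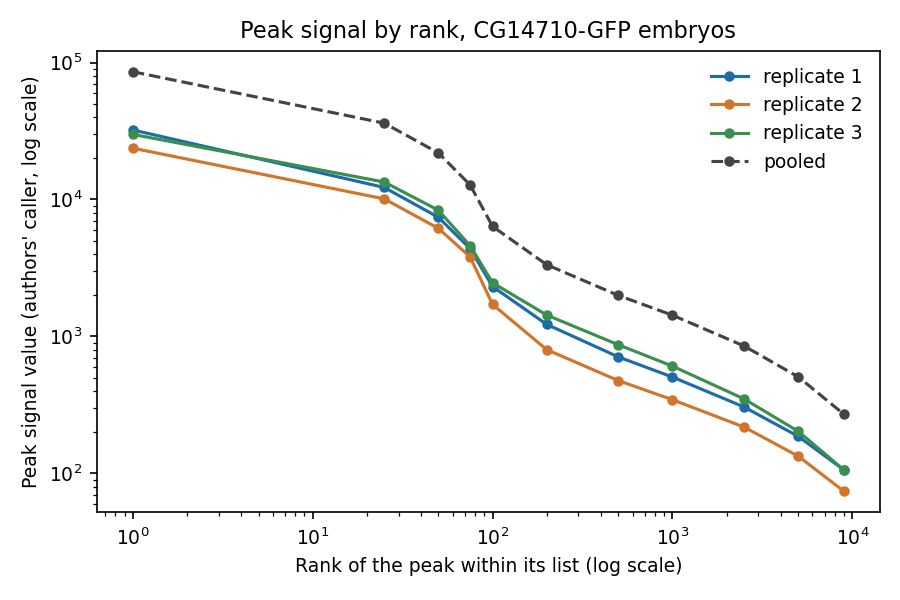
Signal value of the authors' peak caller (log scale) against the rank of the peak within its list (log scale) for the 3 replicate lists and the pooled list, with points at 11 chosen ranks. In every list the signal drops most steeply between ranks 50 and 100, in the pooled list from 21874 to 6358.

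Replicates were compared by how far their strongest peaks coincided. Between pairs of replicates, 78.9% ± 5.07 (SD over 3 pairs) of the 9194 strongest peaks had their summit inside a peak of the other replicate's 9194 strongest, against 2.47% from coverage alone. The pair of replicates 1 and 2 shared 84.3%, replicates 1 and 3 shared 78.0%, and replicates 2 and 3 shared 74.3%. Across IDR peaks, which are not independent replicates, Spearman's rho of the signal was 0.847 between replicates 1 and 2, 0.717 between 1 and 3 and 0.695 between 2 and 3, with a mean of 0.753 ± 0.0824 (SD over 3 pairs). These pairs used the 8770, 8617 and 8583 IDR peaks, in turn, that had a peak in both replicates. The IDR peaks were the 9194 pooled peaks with the highest signal, and the pooled list was made from these same replicates, which favours agreement. Among IDR peaks, 6222 (67.7%, Wilson interval 66.7% to 68.6%) were within the 9194 strongest of all 3 replicates, and 20 were within those of none. The share that was within all 3 moved with the number of peaks taken, from 34.1% at 50% of that number to 90.5% at 2 times that number.

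IDR peaks concentrated at promoters and avoided coding sequence. A summit lay within 500 bp of a TSS for 5330 peaks (58.0%), 4.27 times the 13.6% of bases in such windows. Only 18 peaks (0.196%) had their summit in a coding exon outside these windows, against 13.8% of bases. Introns held 25.8% of summits against 39.4% of bases, intergenic sequence 14.1% against 27.2%, 3' untranslated regions 0.838% against 4.43% and 5' untranslated regions 0.446% against 0.781%. All 6 of these differences passed two-sided exact binomial tests with Benjamini-Hochberg adjustment over 7 classes (largest adjusted p = 0.00013, for 5' untranslated regions), and non-coding exons did not (0.653% against 0.832%, adjusted p = 0.058). In the 9194 strongest peaks of each replicate, the promoter share was 58.9% ± 4.87 and the coding exon share 0.199% ± 0.0412 (SD, n = 3), so both departures from the share of bases were far larger than the spread between replicates. With a window of 250 bp the ratio was 6.6 and with 1000 bp it was 2.76.

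**Figure D2:**
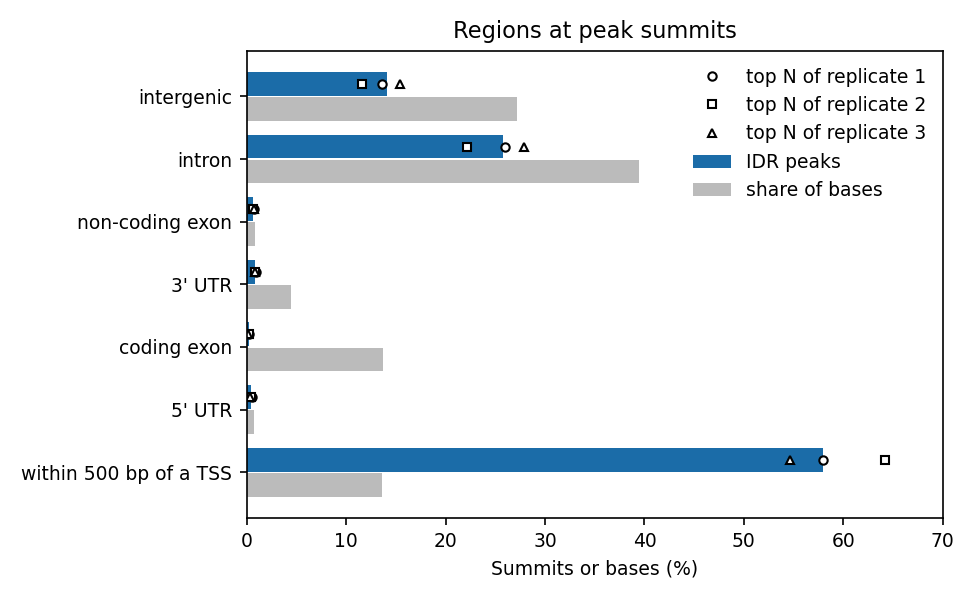
Share of peak summits (blue) and of bases (grey) in each of 7 region classes, in percent, with a point for the strongest 9194 peaks of each replicate. Summits exceed bases in the class within 500 bp of a TSS, 58.0% against 13.6%, and all 3 replicate points lie between 54.6% and 64.2% there.

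Genes of protein synthesis, respiration and cell division carried promoter peaks more often than other genes. Of 13944 protein-coding genes, 5941 (42.6%) had an IDR summit within 500 bp of a TSS. Such genes are called bound here and below. No sample without the tagged protein was analysed here, so enrichment of open promoters without it stays open for these lists. Among cytosolic ribosomal protein genes it was 84 of 92 (91.3%, Fisher adjusted p = 5.62e-22), with RpS3 (8485), RpL23A (2714) and RpS27 (2566) among the members with the highest promoter signals. Among mitochondrial ribosomal protein genes it was 64 of 73 (87.7%, Fisher adjusted p = 5.04e-15), led by mRpL27 (55810, in the interval shared with CG15435), mRpS10 (7447), mRpL41 (5813) and mRpL23 (4332). Oxidative phosphorylation genes were bound in 63 of 87 cases (72.4%, Fisher adjusted p = 5.5e-08), with the complex III gene UQCR-C1 at 22166 and the complex I genes ND-B14.7 and ND-18 at 18074 and 13746, followed by COX4 at 3289. Proteasome genes were bound in 30 of 48 cases (62.5%, Fisher adjusted p = 0.0114), led by the regulatory particle genes Rpn7 (21968) and Rpt3 (20368), then Prosbeta2 (1470) and Rpn5 (1453). For spliceosome and translation factors it was 43 of 60 (71.7%, Fisher adjusted p = 1.91e-05), with eIF4H1, snRNP-U1-70K (12768), eIF4EHP (5263) and eIF2alpha (3208) highest. For cell cycle and replication genes it was 31 of 35 (88.6%, Fisher adjusted p = 5.5e-08), with the origin recognition gene Orc4 (8345), Cyclin E (CycE, 2699), aurA (1662) and Cdk1 (1290) highest.

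Genes of chromatin proteins also carried promoter peaks more often. Insulator and architectural protein genes carried a promoter peak in 15 of 17 cases (88.2%, Fisher adjusted p = 0.000406), with Chro, whose start site shares the Ssl1 peak (40727), Cp190 (4290), M1BP (2115) and pzg (1765) highest. Polycomb and trithorax group genes, which maintain silent and active states of developmental genes, were bound in 18 of 24 cases (75%, Fisher adjusted p = 0.00274), with the methyltransferase gene ash1 at 26531, ph-p at 5064, brm at 3122 and E(z) at 2237. For genes of zinc finger proteins with a zinc-finger-associated domain (ZAD), a list that held CG14710 itself, it was 14 of 20 (70%, Fisher adjusted p = 0.0287), with CG14711 (3309), M1BP, hang (1811) and CG14710 (1804) highest. The CG14711 peak lay within 20 kb of CG14710, at the tagged gene's locus. The ZAD and insulator lists share members, M1BP among them, so they are not separate support.

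The lists bound less often than other genes were chemosensory receptors, cuticle proteins, replication-dependent histones, chorion, yolk and seminal fluid genes, and segmentation genes. Chemosensory receptor genes carried a promoter peak in 2 of 179 cases (1.12%, Fisher adjusted p = 6.82e-39), at Gr63a (495) and Ir60e (358). No peak lay at the promoters of 97 cuticle protein genes (upper Wilson bound 3.81%, Fisher adjusted p = 2.88e-23) or of 111 replication-dependent histone genes (upper bound 3.35%, Fisher adjusted p = 1.53e-26). With a window of 1000 bp, 5 of the 97 cuticle protein genes were bound and the call stayed (odds ratio 0.0686, Fisher adjusted p = 1.65e-18). The histone genes are near-identical repeated copies, so whether reads could be placed there is uncertain. The list of chorion, yolk and seminal fluid genes was bound in 3 of 59 cases (5.08%, Fisher adjusted p = 3.34e-10). Its highest member was Cp190, an insulator protein gene taken in by its name, and the others were Sfp26Ad (1006) and Sfp24F (469); without Cp190, a choice made after seeing the data, it was 2 of 58 (3.45%). Segmentation genes, which pattern the early embryo, were bound in 3 of 23 cases (13.0%, Fisher adjusted p = 0.00766), at nkd (1698), ci (331) and cad (298). In the strongest peaks of single replicates the segmentation call passed only in replicate 3. With IDR peaks restricted to the strongest of replicates 1 and 2 it stayed (Fisher adjusted p = 0.0235).

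For 5 lists no difference passed the test. Dorsoventral and mesoderm genes were bound in 4 of 20 cases (20%, Fisher adjusted p = 0.0548), with stumps (3148) and tin (2082) highest, and neural genes in 6 of 22 (27.3%, Fisher adjusted p = 0.232), with elav (3461) and N (564) highest. The values were 2 of 8 for Hox genes (lab 408, Antp 299), 12 of 28 for heat shock and chaperone genes (Hsp27 2596, Hsc70-5 1946) and 10 of 19 for germline genes (cuff 1747, gcl 1233). With a promoter window of 250 bp the Hox (0 of 8, Fisher adjusted p = 0.0328), dorsoventral and mesoderm (2 of 20, 0.0148) and neural (3 of 22, 0.0302) lists passed as bound less often. All p-values for the 19 lists came from two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the 19. In the 9194 strongest peaks of each replicate, promoter peaks stood at 89.1% ± 1.09 of cytosolic ribosomal protein genes and at 42% ± 1.18 of all protein-coding genes (SD, n = 3). Segmentation genes were the least even list, with 30.4%, 30.4% and 4.35% bound in replicates 1, 2 and 3.

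Calls for several lists depended on the background genes. Against the 7684 genes with a summit of the authors' pooled list at the promoter, which include all 5941 bound genes, 8 lists passed instead of 14. The odds ratio moved toward or past 1 and the call ended for the insulator (1.82, Fisher adjusted p = 0.511), ZAD (0.946, 1), Polycomb and trithorax (1.21, 0.85), cell cycle (2.06, 0.239), chorion (0.293, 0.229) and spliceosome (1.51, 0.443) lists. For the proteasome list the call ended (Fisher adjusted p = 0.118) with 33 members in place of 48, while the odds ratio was 2.57 against 2.23. No histone gene was in that background. The dorsoventral and mesoderm list (odds ratio 0.155, Fisher adjusted p = 0.00398) and the neural list (0.2, Fisher adjusted p = 0.00491) passed there as bound less often. Among the 7241 genes without a TSS of another gene within 1000 bp, the calls ended for the proteasome list (odds ratio 2.2 with 22 members, Fisher adjusted p = 0.132), the segmentation list (0.445, 0.388) and the ZAD list (1.42 with 7 members, 0.815). With a window of 1000 bp the ZAD odds ratio was 2.61 against 3.01 (Fisher adjusted p = 0.0568). The odds ratio of 9.23 for mitochondrial ribosomal protein genes was 3.93 in the 50% of peaks with the higher signal, 3.61 among genes without a near TSS and 2.54 with the pooled background, all past the threshold. In the same 50% of peaks it was 4.61 against 9.47 for cell cycle genes and 2.09 against 3.52 for oxidative phosphorylation genes, also past it. With IDR peaks restricted to those among the 9194 strongest of the remaining 2 replicates, the odds ratio for mitochondrial ribosomal protein genes moved to 4.59 without replicate 1 and 5.38 without replicate 2, and that of 0.23 for segmentation genes to 0.116 and 0.118. Without replicate 3 the odds ratio for segmentation genes was 0.274 and the call stayed (Fisher adjusted p = 0.0235). For insulator protein genes the odds ratio of 8.37 moved to 5.24, 5.35 and 4.83 without replicates 1, 2 and 3. The IDR list was itself made from all 3 replicates, so these values do not remove a replicate fully. In the 9194 strongest peaks of each replicate alone, an alternative added after seeing the data, the segmentation call ended in replicate 1 (odds ratio 0.631, Fisher adjusted p = 0.333) and replicate 2 (0.595, 0.347) and passed only in replicate 3 (0.0959, 0.000249), while the other 13 lists passed in each replicate.

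**Figure D3:**
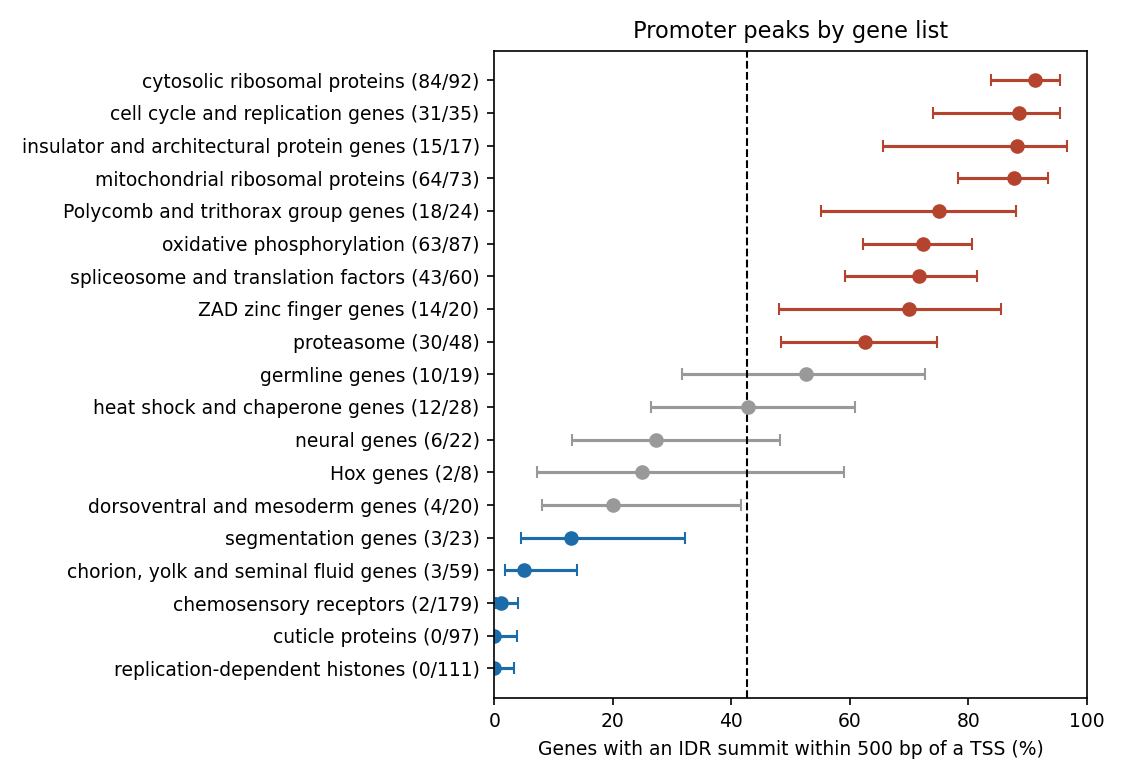
Percent of genes in each of 19 lists with an IDR summit within 500 bp of a TSS, with 95% Wilson intervals; counts stand beside the names and the dashed line marks 42.6% of all protein-coding genes. Red lists were bound more often and blue lists less often after adjustment, grey lists did not pass, and the values run from 0 of 111 histone genes to 84 of 92 cytosolic ribosomal protein genes.

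Summits carried sequences known as those that other promoter and boundary proteins recognize, and whether the tagged protein binds them was not tested. The M1BP sequence GGTCACACT, also known as core promoter motif 1, lay within 50 bp of 2.55% of summits against 0.0761% of same-peak flanks 500 bp away (odds ratio 31.3). The DREF sequence TATCGATA lay at 4.38% against 0.196% (odds ratio 23), the ZIPIC sequence CAGGGCTG at 1.09% against 0.109% (9.57), the CTCF sequence AGRKGGCGC at 1.15% against 0.272% (4.18) and core promoter motif 6, GGTATTTT, at 2.57% against 0.631% (4.15). Over the 9194 strongest peaks of each replicate, the DREF sequence was at 4.12% ± 0.479 of summits and 0.228% ± 0.0219 of flanks (SD, n = 3). In all, 12 of 22 fixed motifs were enriched and 4 depleted by two-sided exact McNemar tests with Benjamini-Hochberg adjustment. The depleted ones were the GAF sequence GAGAGAG (0.935% against 2.47%), the Zelda sequence CAGGTAG (0.348% against 0.718%), the E-box CACGTG and the initiator. The initiator call (8.01% against 8.89%, odds ratio 0.891) ended under every alternative but that without replicate 1, with an odds ratio from 0.836 at peaks further than 500 bp from a TSS to 1.04 against shuffled windows, and 0.893 in the 50% of peaks with the higher signal. Comparing left with right flanks, none of the 22 passed by the same test, and 2 had an unadjusted p under 0.05.

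Several of these calls depended on base composition or on promoters. The TATA box (6.62% of summits), the GATA sequence (16.1%) and the Hox homeodomain sequence TTAATTA (6.35%) were enriched over flanks but had odds ratios of 0.912, 0.795 and 0.837 against dinucleotide-shuffled copies of the same windows. GAF turned the other way, with an odds ratio of 2.26 against shuffled windows, and the Zelda call ended there (0.813, adjusted p = 0.537 by the exact test). The E-box CAGCTG, with an odds ratio of 0.934 over flanks, was enriched there (3.41, adjusted p = 2.42e-37 by the exact test), and CTCF had 16.4. Of the 12 motifs, 9 were enriched against both backgrounds. Among these, the Twist E-box (odds ratio 1.23), lost its call at a similar odds ratio in the 50% of peaks with the higher signal (1.29, adjusted p = 0.0562) and without the 100 strongest peaks (1.19, 0.0538), and also without soft-masked summits (1.15, 0.17), without replicate 1 (1.15, 0.209) and without replicate 2 (1.14, 0.204), by the exact test. At peaks further than 500 bp from a TSS 7 motifs were enriched, and GAF, CACGTG and CAGCTG were depleted: the DREF odds ratio was 2.69 (adjusted p = 0.0587 by the exact test), that of motif 6 was 1.41 (adjusted p = 0.29), M1BP stayed enriched at 8.2, and those of the BEAF-32 core CGATA, motif 7 and ZIPIC were 0.966, 0.846 and 0.867. M1BP had an odds ratio of 15.2 with windows of 100 bp on each side and 75.8, over 2 flanks with the sequence, without replicate 1; ZIPIC had 16.1 without replicate 1, and Su(Hw) 6.64 in place of 3.44 without replicate 2.

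**Figure D4:**
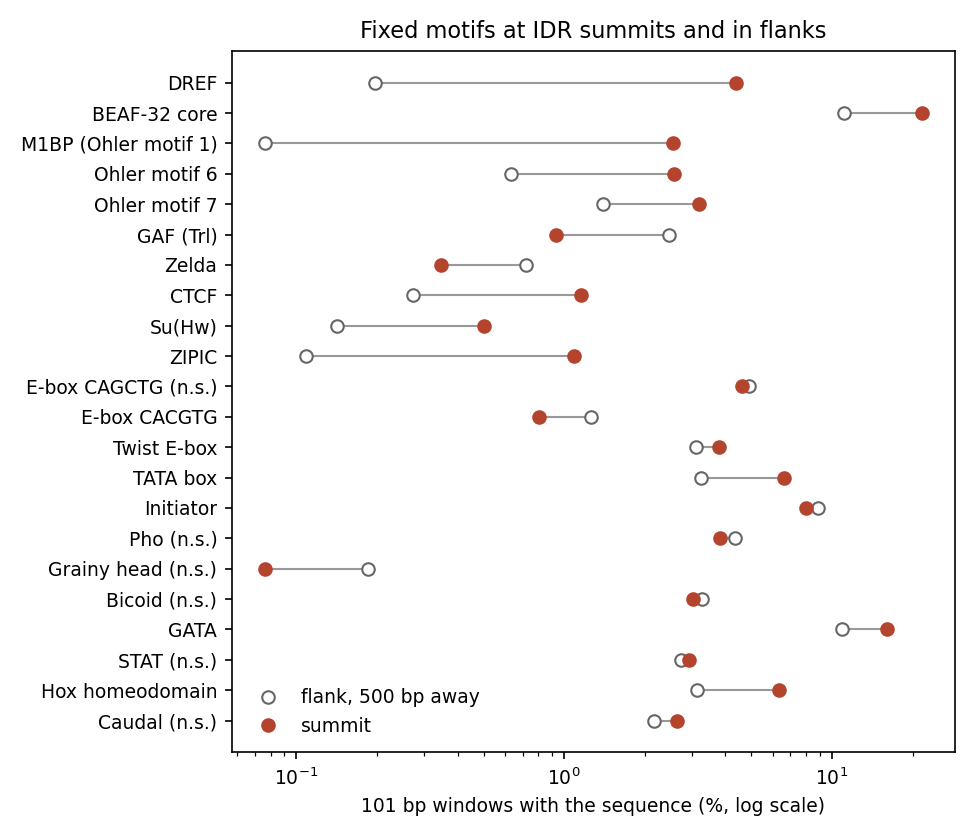
Percent of windows of 50 bp on each side (log scale) that hold each of 22 fixed motifs at IDR summits (filled) and in the flank 500 bp away (open); motifs that did not pass are marked n.s. The widest gaps are those of M1BP, 2.55% against 0.0761%, and DREF, 4.38% against 0.196%.

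An open search found 8-mers of the DREF and M1BP sequences and 8-mers of only A and T. The 20 8-mers with the smallest p on 2L, 2R and 4 (3436 peaks) were tested again on 3L, 3R, X and Y (5758 peaks), and all 20 were enriched there (largest adjusted p = 3.06e-17, exact McNemar tests with adjustment over 20). The 5 with the largest odds ratios were TATCGATA (23.8), GTTATCGA (20.3), ATCGATAG (16.2), GGTCACAC (15.6) and AGTGTGAC (15.3). Without replicate 1 the odds ratio was 59.8 for GGTCACAC and 27.9 for AGTGTGAC, and without replicate 3 it was 12.2 for GTTATCGA, which was not among the 20 without replicate 1 or 2. The first 3 overlap the DREF sequence and the last 2 the M1BP sequence. A further 12 of the 20 held only A and T, and rose 2.1 to 4.85 times over flanks. Against shuffled windows 20 8-mers also passed, of which 9 were shared with the first search: the 8 that hold the DREF or M1BP sequences and 1 of only A and T, AATAAATA (odds ratio 1.85). GTTATCGA had an odds ratio of 6.03 there and GGTCACAC 29.9. At peaks further than 500 bp from a TSS the 5 shared 8-mers held only A and T.

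Promoter peaks had more signal than other IDR peaks in each replicate. The ratio of medians was 1.24, 1.62 and 1.3 in replicates 1, 2 and 3, a mean of 1.39 ± 0.205 (SD, n = 3), above 1 in 3 of 3. The exact two-sided sign-flip test gave p = 0.25, which is the smallest that 3 replicates allow. Chromosome arms differed little: 2L had 1.07, X 1.07 and 3L 1.06 times the peaks of their length (adjusted p = 0.00326, 0.00511 and 0.00595, exact binomial tests), while the small chromosome 4 had 0.638 times (57 peaks, adjusted p = 0.00124). No IDR peak lay on Y, where repeats limit the placing of reads. The excess on X was lost in the 50% of peaks with the higher signal (0.945), and that on 2L turned to 0.953 when arms were weighted by TSS number, where 2R had 0.889 times (adjusted p = 9.23e-08, exact binomial test). The deficit on chromosome 4 lost its call with TSS weighting (0.814, adjusted p = 0.155, exact binomial test). With the authors' pooled list as background the calls ended for 2L (1.003, adjusted p = 0.893), 3L (0.962, 0.15), X (0.963, 0.168) and 4 (0.816, 0.199), and 3R passed at 1.07 (0.00312), by the same exact test.

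The tagged gene had a peak at its own promoter. CG14710 (FBgn0037920) lies on 3R, 11620090 to 11621728, on the forward strand. The IDR peak at 11619773 to 11620212 had its summit at -77 bp from its TSS and a pooled signal of 1804, rank 627 of the list. In replicates 1, 2 and 3 the corresponding peak stood at the 97.3, 98.8 and 97.5 percentile of the list. Within 20 kb on each side there were 6 IDR peaks, against a median of 4 in windows of the same width around 13921 protein-coding genes, and 35.3% of those windows held as many. The strongest of the 6 lay at the promoters of Zaf1 and CG14711 (3309), followed by the CG14712 promoter (2286). No IDR summit lay in the gene body of CG14710. The line was transgenic, and whether an extra copy of this locus added to its signal was not tested.

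**Figure D5:**
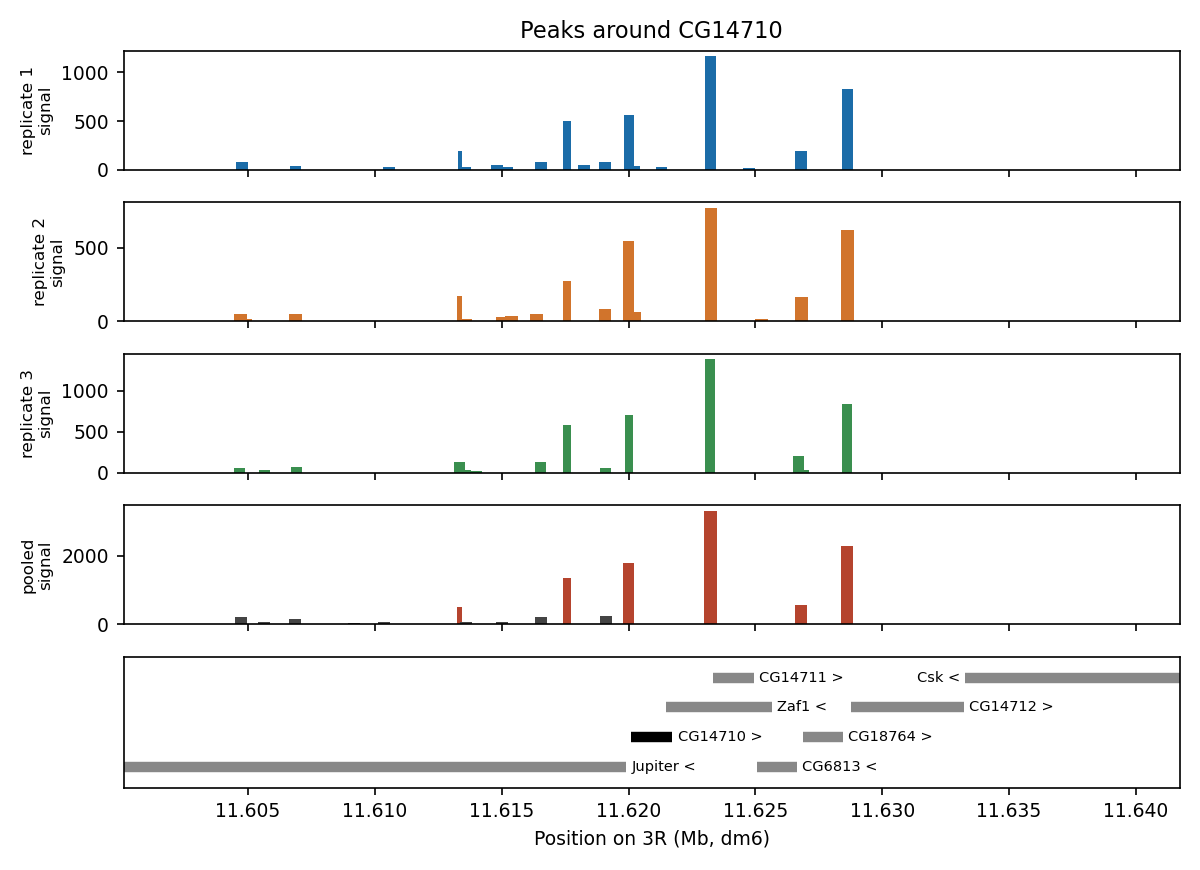
Peaks of each replicate list and of the pooled list (IDR peaks in red) around CG14710 on 3R, with the signal of the authors' caller on the y axis and position in Mb (dm6) on the x axis; protein-coding genes are drawn below with their strand. The peak at the CG14710 promoter reaches 1804 in the pooled list, below the 3309 of the peak at the Zaf1 and CG14711 promoters.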

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

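No test was run on the following result, which lies outside the chromosome arms used for the comparisons of regions, genes and motifs. Replicate 2 had 10 peaks on the mitochondrial genome, at percentiles of 57.7 to 99.8 of its list, while replicates 1 and 3 and the pooled list had 0 there. These peaks were not removed from the ranking by signal or from the overlap between replicates. Of the 9194 strongest peaks of replicate 2, 9185 lay on the arms.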

How the results depend on the processing

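The alternatives without the 100 strongest peaks, without the histone genes, without Cp190, with the overlap of the 100 strongest peaks of each replicate, and with gene lists in each replicate alone were chosen after seeing the data. Promoter enrichment stayed past the threshold in every setting run, between 2.76 and 6.6 times, and the 20 8-mers picked under each of the 8 alternatives run for them were enriched on the held-out arms, except that without soft-masked summits it was 19, and AGCAGCAG was depleted. Keeping the 50% of peaks with the higher signal left 4597 IDR peaks, a promoter to distal signal ratio of 1.12 and a ratio of 0.945 on X. The overlap between replicates was 72.4% with 2 times as many peaks, 67.5% when 50% of both intervals had to overlap and 93.3% for the 100 strongest; without each replicate it ranged from 74.3% to 84.3%, and rho from 0.695 to 0.847. The share of IDR peaks among the strongest of every replicate was 34.1% with 50% of the list size, 90.5% with 2 times the list size and 49.4% with overlap of 50% of both intervals, and 72.1% to 78.5% without a replicate, where fewer lists had to hold the peak. With the pooled list as background, 1 arm, 3R, passed instead of 5, with ratios of 0.962 on 3L and 0.963 on X, and 8 gene lists passed, with an odds ratio of 0.946 for the ZAD list. Without genes near another TSS, the insulator list had too few members to test. Weighting arms by TSS gave 0.953 on 2L. Against shuffled windows, odds ratios turned to 2.26 for GAF, 0.912 for the TATA box, 1.04 for the initiator, 0.795 for GATA and 0.837 for the Hox sequence. At peaks further than 500 bp from a TSS, 7 motifs were enriched, and odds ratios were 0.966 for BEAF-32, 0.846 for motif 7 and 0.867 for ZIPIC. The CG14710 gene body held 0 IDR peaks. Leaving a replicate out restricts an IDR list made from all 3, so it shows only part of that replicate's weight. The cause was not tested for any other change. Among single arms, lists and motifs past the threshold, 307 values under alternatives kept direction and call, 31 kept direction only and 13 reversed. Read depth is unknown, so what it limits cannot be stated.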

Other observations

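The tests in this part were chosen after the results they concern were seen, except those of replicate 3 within GC content and within promoter and distal peaks, which were written down before their values were computed, although the rise of the gap with GC over all peaks had been seen. A promoter peak was present at 12.2% of 1987 long non-coding RNA genes (10.8% to 13.7%), 32 of 290 tRNA genes (7.93% to 15.2%), 6.69% of 269 small nucleolar RNA genes (4.27% to 10.3%) and 8 of 32 small nuclear RNA genes (13.3% to 42.1%), next to 42.6% of protein-coding genes; these shares were not tested against each other. None of 98 ribosomal RNA genes had one, and tRNA and ribosomal RNA genes include repeated copies where placing reads is uncertain. Of the promoter peaks among the 100 strongest, 48% lay between divergent genes, against 37.5% of 5232 weaker promoter peaks (Fisher's exact test, p = 0.0357). Replicate 3 had 1 peak on Y, at percentile 24.5 of its list.

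The 100 strongest sites carried a gapped sequence, AGTGTNNNCACAC, within 100 bp of 41 summits (31.9% to 50.8%) and of 0 flanks 1500 bp away, and in the 100 strongest of each replicate it was at 40% ± 1 (SD, n = 3). The replicates also made up the pooled peaks that the search used, so this spread is not separate support. The sequence was picked by a search on 2L, 2R and 4 and was at 23 of 65 sites and 0 flanks on the other arms (adjusted p = 2.38e-06, exact McNemar test), although 4 hand-written forms had been tried and sequences from all arms looked at beforehand. Promoter position alone is argued against by 0.306% of 5232 weaker promoter peaks carrying it, and base composition by 0 of 1000 shuffled windows (upper bound 0.383%). Near-identical copies of a longer repeated element are argued against by 0 of 41 windows sharing a 16-mer outside the sequence (upper bound 8.57%). Diverged copies need not share an exact 16-mer, so they stay open. A first form of the repeat test, with 48.8% of windows sharing a 16-mer, included the sequence itself and leaves a short repeat open. The sequence by itself, wherever it lies, is argued against as sufficient, since only 17.5% of 194 copies away from promoters (12.8% to 23.5%) lay within 500 bp of an IDR peak. Of the promoter copies, 73 of 89 did. However, 46 of these 89 lay within 500 bp of the 100 strongest sites, from which the sequence was picked, so that share was partly set by the choice. With 1 group, no biological explanation was tested.

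Sites below the 100 strongest also carried sequences known from other proteins. Exact copies of the gapped sequence were at 0.374% of the 9094 peaks below the strongest 100, against 41 of the 100 strongest. Looser matches were not counted, so the share of weaker sites that a form of it accounts for cannot be told. With GAC in its middle, as in 5 of 46 copies, the gapped sequence holds the M1BP sequence. The DREF or M1BP sequence was at 6.58% of the 9094 peaks and 0.33% of flanks, against 21 of the 100 strongest (14.2% to 30%) in the same windows. Enrichment of open promoters without the tagged protein could give this too and stays open, because no sample without the tagged protein was analysed here.

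Replicate 3 ranked sites apart from the other replicates, with a mean rho of 0.706 to them against 0.847 between replicates 1 and 2, a gap of 0.141. Within 10 bins of GC content the mean rho was 0.729 against 0.852, which argues against differences between bins as the whole cause, but the gap was 0.0339 and 0.0444 in the 2 bins lowest in GC and 0.215 in the highest. An effect that grows with GC content is consistent with the gap rising over the bins within promoter peaks (rho 0.83, permutation p = 0.00484) and within the others (rho 0.964, permutation p = 2e-05, the smallest they can give). The balance of promoter and distal sites is argued against as the whole cause, with 0.754 against 0.86 within promoter peaks and 0.616 against 0.85 within the others. Read depth is unknown and may differ between replicates, so it stays open.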
